A study of Mus musculus with 12 samples.

How the data were processed

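H3K4me3 and H3K27me3 were profiled by CUT&Tag in 12 libraries of mouse mammary tumour organoids derived from the PyMT tumour model, taken 3 days after treatment. The 6 groups were Ctrl, SR2 and THC for each of the 2 marks, with 2 replicates per group. The treatment names are those of the labels, and what SR2 stands for is not given in the sources used here. Each library came from 500000 cells immobilised on concanavalin A beads, with 60 min of tagmentation by a protein A fusion of Tn5 and 150 bp paired-end reads, per the labels' protocols. The protocol given with the samples and the design text of the series name different enzymes for dissociation, so the dissociation step is left open here.

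The submitters' processing notes name cutadapt 5.2, Bowtie2 2.5.4, Picard, SAMtools 1.8, deepTools, MACS3 and bedtools, and the mouse build mm10, without giving their roles or order. The deposited values are peak lists, 1 per library, and the peak names carry the name of a single library, so the authors called peaks per sample and not on pooled samples. H3K4me3 lists are narrow peaks and H3K27me3 lists are broad peaks. Each deposited line gives the start and end of a peak, a score, a fold enrichment over the caller's background, and the −log10 p and −log10 q of the peak. In the deposited lists the score was the whole part of 10 times the −log10 q in 99.886% of lines in the library with the lowest share. The authors' fold enrichment is a ratio within 1 library, and the authors' −log10 q values reached down to 1.30 in the H3K4me3 lists and 1.00 in the H3K27me3 lists. These values per peak are the authors' own and were used only to describe, rank or filter peaks within a list.

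Peak lists hold no read totals. In the H3K4me3 lists the pileup at each summit and the local background could be recovered from the deposited fold enrichment and −log10 p, because at least 99.99% of summit pileups came out as whole numbers within a tolerance of 0.005. The lowest, genome-wide background pileup was 1.05 and 1.02 in the Ctrl libraries, 1.16 and 1.10 in the SR2 libraries, and 0.752 and 1.52 in the THC libraries (replicates 1 and 2). The depth of the H3K27me3 libraries is unknown.

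Only chromosomes 1 to 19, X and Y were used. Peaks of the 6 libraries of a mark were merged where they overlapped by at least 1 bp, which gave 24596 H3K4me3 and 4187 H3K27me3 consensus regions, and the bp of each region covered by each library's peaks were computed. Gene positions came from the NCBI RefSeq gene table of GRCm38.p6, the assembly of mm10, which holds 49997 genes, 49939 of them with a position on these chromosomes and 21883 of these protein-coding. The table used here gives neither strand nor transcription starts, so the design written for promoters was carried out on consensus regions, as that design allows for this case. A gene was given the H3K4me3 region with the most covered bp among those within 1 kb of either gene end. An H3K27me3 region was given to a protein-coding gene when it overlapped the gene or its 5 kb of flank. Exons, introns and untranslated regions were not analysed here.

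Replicates were compared before they were averaged. A chi-square test of summit pileups over 5069 strong H3K4me3 regions gave 0.894, 0.997 and 0.806 per degree of freedom for the replicate pairs of Ctrl, SR2 and THC. The 12 pairs of libraries of different groups gave 0.768 to 1.59, 4 of them below 1, so no replicate pair stood apart and each group kept n = 2. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. The replicate number is also the batch number in the labels, so the labels pair the samples of different groups. In the data the correlation of the deviations of same-numbered samples was −0.0619 for Ctrl and SR2, 0.0344 for Ctrl and THC and 0.0479 for SR2 and THC, over 15772 regions.

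Peak numbers and covered lengths per library were compared by exact two-sided permutation tests. A control-only region had a peak in both Ctrl libraries and in neither library of a treatment, and a treated-only region the reverse. Their numbers were set beside those from the other 2 ways of splitting the same 4 libraries into pairs, the split by batch and the crossed split. H3K4me3 breadth was tested with limma 3.58.1 (trend, in R 4.3.3) on log2(covered bp + 200), in 1 fit of all 6 libraries, for 15772 regions marked in at least 2 libraries. Libraries were centred on their median over the 10140 regions marked in all 6, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. These log2 changes understate the difference where a library has no peak. Changes of breadth are relative to the centring, without which the median change was −0.17 for SR2 against Ctrl, −0.52 for THC against Ctrl and −0.27 for THC against SR2.

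The 19 gene lists (531 gene symbols, all matched) were luminal hormone sensing, luminal progenitor and alveolar, basal and myoepithelial, epithelial mesenchymal transition, epithelial junction and adhesion, stemness and plasticity, Wnt and Notch signalling, cannabinoid system, cell cycle, immediate early and stress, sterol and lipid metabolism, interferon and antigen presentation, developmental transcription factors, chromatin modifiers of the 2 marks, ribosomal proteins, and markers of fibroblasts, leukocytes, endothelium and adipocytes. They were tested with camera on the breadth fit with a preset correlation of 0.01, with Fisher's exact test among control-only and treated-only regions, and against 10000 random lists matched on peak strength. The breadth of list genes was also adjusted over the list alone. That adjustment was made within each list and comparison and not over the 19 lists, so it is lenient, most of all for short lists. The overlap of genes with both marks was tested per pair of libraries with Fisher's exact test, and the number of shared control-only regions was set beside 100 simulations with no effect. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all else.

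The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule took, per treatment, up to 15 list genes per direction with a control-only or treated-only H3K4me3 region and up to 8 other protein-coding genes per direction without a clone name, both by covered bp. It also took up to 2 genes per list marked in all 6 libraries, up to 10 H3K27me3 regions per direction, up to 15 list genes in such regions, up to 10 list genes with both marks in both Ctrl libraries, and 12 genes always named. Other genes are named because their breadth passed the threshold over the list alone, or were chosen after their values were seen where that is stated. Some genes that these rules select are not reported here. Alternatives covered the authors' peak threshold, equal numbers of peaks (11924 per H3K4me3 library), overlap, pseudocount, filters, centring, the replicate block, the libraries in the fit and leaving out each library.

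The breadth test and a model of weaker enrichment were tested on simulated data. For SR2 against Ctrl, with 200 of 15772 regions narrowed and the real spread kept, limma called 0% of falls of 1 on the log2 scale, 29% of falls of 2 and 52% of falls of 4. With a residual SD of 0.1 for every region it called 100% of falls of 1, whereas the real median residual SD was 0.211. The enrichment model, run on 14611 regions, predicted 1.07 times the simulated number of control-only regions for SR2 and 0.998 times for THC. These simulated libraries were drawn from the model itself, so the values check the code and not whether the model holds for real libraries.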

Results

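The libraries mapped H3K4me3, a mark of active promoters, and H3K27me3, a mark of Polycomb repression, in PyMT tumour organoids, also called spheroids in the labels, given a control treatment (Ctrl), SR2 or THC, 2 libraries per mark and treatment. The title of the series asks about modulation of the cannabinoid receptor CB2R, encoded by Cnr2, and about luminal differentiation and plasticity. The Ctrl H3K4me3 libraries held 18383 and 16442 peaks, the SR2 libraries 14812 and 15190, and the THC libraries 11924 and 13229. The H3K27me3 lists were far shorter, with 2712 and 387 peaks in Ctrl, 840 and 157 in SR2, and 984 and 70 in THC (replicates 1 and 2). Of the 24596 H3K4me3 regions, 10140 (41.2%) were marked in all 6 libraries, but 3635 of the 4187 H3K27me3 regions (86.8%) were marked in a single library.

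**Figure D1:**
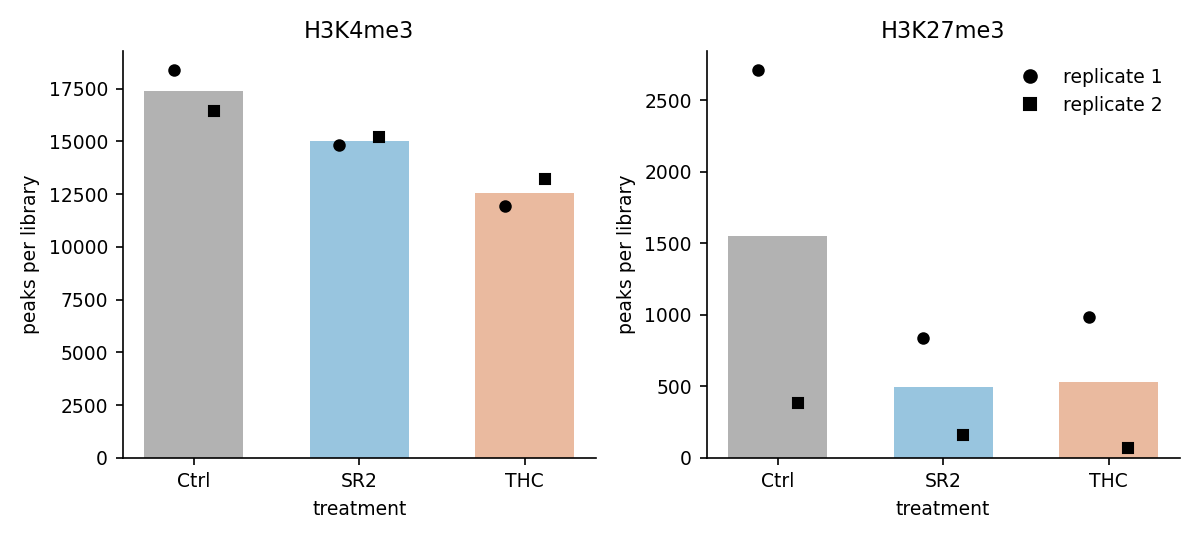
Peaks per library (y axis, number) by treatment (x axis) for H3K4me3 and H3K27me3; bars are means of 2 libraries, and the circle and the square are replicates 1 and 2. All 4 treated H3K4me3 libraries, with 11924 to 15190 peaks, lie below the Ctrl libraries, while the H3K27me3 replicates of Ctrl range from 387 to 2712.

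The cannabinoid receptor genes and most genes of the luminal and basal lists had an H3K4me3 region within 1 kb of a gene end. Without strands, that end may not be the start of the gene. The region given to Cnr2 was marked in all 6 libraries, with 1637.5 ± 65.8 bp in Ctrl, 1555.5 ± 131 bp in SR2 and 1063 ± 229 bp in THC (covered bp, mean ± SD, n = 2 here and throughout). The region (mm10 chromosome 4, 135920380 to 135922090) is shared with Fuca1. Whether the mark belongs to Cnr2 or to Fuca1 cannot be told from the gene table used here, which gives no strand. The values of this region are therefore not evidence of H3K4me3 at the start of Cnr2. By limma the log2 change of its breadth was 0.07 for SR2 (adjusted p 0.944) and −0.17 for THC (adjusted p 0.229) against Ctrl. Cnr1, the other cannabinoid receptor, was marked in 5 libraries and had no peak in THC replicate 1. The luminal keratin gene Krt8 and the H3K27 methyltransferase gene Ezh2 were marked in all 6 libraries, with 1628.5 ± 0.707 and 1524.5 ± 46.0 bp in Ctrl. The basal keratin genes Krt5 (1933 ± 240 bp in Ctrl) and Krt14 (2340.5 ± 110 bp in Ctrl), the luminal regulator gene Gata3 and the mesenchymal filament gene Vim each lacked a peak only in THC replicate 1. Esr1, the oestrogen receptor gene, had 563 and 328 bp in Ctrl, 414 bp in SR2 replicate 2 and no peak in the other 3 libraries. Foxa1, Trp63 and Elf5 had no H3K4me3 region within 1 kb of either gene end.

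SR2 was compared with Ctrl to ask where H3K4me3 differs after this treatment. The list genes marked in both Ctrl libraries and in neither SR2 library came from several lists, none of which passed Fisher's exact test with all libraries. Cdh2 (N-cadherin) had 939.5 ± 624 bp in Ctrl, Fn1 (fibronectin) 836.5 ± 265 bp, and Tnc (tenascin C) 716.5 ± 257 bp, each against 0 bp in both SR2 libraries, and they made up 3 of the 17 marked genes of the epithelial mesenchymal transition list. The breadth of H3K4me3 at Sqle, which encodes squalene epoxidase of cholesterol synthesis, fell from 2594.5 ± 177 to 1119.5 ± 98.3 bp, a log2 change of −0.94 (SE 0.07) with an adjusted p of 0.000464 over the list alone. The other control-only list genes were Cxcl12 (764.5 ± 531 bp), a chemokine gene of stromal cells, the Notch target gene Heyl (592.5 ± 61.5 bp), Ptgs2 (589 ± 356 bp), Foxf1 (565 ± 359 bp), Sox2 (494 ± 38.2 bp), Lgr5 (441.5 ± 245 bp), Cd68 (370 ± 29.7 bp, a region shared with Eif4a1) and Lhx2 (355.5 ± 96.9 bp).

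Outside the lists, control-only genes of SR2 with broad Ctrl regions included Galnt6 (1384.5 ± 99.7 bp), Dsc3 (1160 ± 60.8 bp), Ly6d (984.5 ± 146 bp), Enho (983.5 ± 670 bp), Slc5a1 (926.5 ± 12.02 bp), Grrp1 (910 ± 173 bp, shared with Gm30191) and Ap1b1 (870.5 ± 30.4 bp, shared with Nefh). Galnt6 encodes a glycosyltransferase, Dsc3 a desmosomal cadherin and Slc5a1 a sodium-dependent glucose transporter. In the other direction, 2 protein-coding genes were marked in both SR2 libraries and in neither Ctrl library, Cfap100 (388.5 ± 13.4 bp in SR2) and a clone-named gene that the rule leaves out. No list gene was SR2-only.

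Over all regions, 1146 of the 14612 marked in both Ctrl libraries (7.84%) were control-only for SR2, and 31 were SR2-only. The total of 1177 compares with 330 for the split of the same libraries by batch and 478 for the crossed split. The control-only regions lay within 1 kb of a gene end in 18.8% of cases (215), against 79.7% of the regions marked in all 4 libraries (Fisher's exact test over regions, odds ratio 0.0589), and 44.7% lay inside genes. They affected 193 protein-coding genes. With 11924 peaks from each library, 139 regions were control-only and 68 SR2-only, a total of 207 beside 212 for the split by batch, and 0 of the 19 control-only genes named for SR2 remained so. Of these 19 genes, 10 remained control-only with peaks of −log10 q of at least 5 and 11 with at least 500 bp covered.

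With limma, 0 of 15772 regions differed in breadth between SR2 and Ctrl after adjustment, while 103 were wider and 1405 narrower at an unadjusted p under 0.05 (smallest adjusted p 0.122). Adjusted over the list alone, 4 of 347 tests of list genes passed, all narrower in SR2. These were Sqle; Pkp3, a desmosomal plaque gene (−0.65, SE 0.08, adjusted p 0.00419); Cxcl12 (−2.01, SE 0.46, adjusted p 0.0212); and Heyl (−1.85, SE 0.33, adjusted p 0.0429). The Sqle call held in all 16 other settings measured, and the Heyl call did not hold with the replicate block (adjusted p 0.110). Leaving out SR2 replicate 1 took the adjusted p of Pkp3 to 0.0638, of Cxcl12 to 0.0702 and of Heyl to 0.151. Without SR2 replicate 2 it was 0.0697 for Cxcl12 and 0.0757 for Heyl. Leaving out Ctrl replicate 2 took Pkp3 to 0.0679, and leaving out THC replicate 1 or 2 took Heyl to 0.122 and 0.106. Quantile normalization ended the calls of Cxcl12 (−1.26, adjusted p 0.178) and Heyl (−0.82, adjusted p 0.466), as did a pseudocount of 1000 bp (adjusted p 0.0506 and 0.156). Heyl also missed 0.05 over regions marked in at least 1 library (0.254) and with only the 4 libraries compared (0.104), and without centring Pkp3 did (0.0728). For genes with 0 bp in SR2 the size of the log2 change follows from the pseudocount, and was −3.52 with 50 bp and −0.58 with 1000 bp at Heyl. With a pseudocount of 50 bp limma called 1059 regions and without centring 994, nearly all narrower.

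THC was compared with Ctrl in the same way. Single genes of lipid handling, Notch signalling and the mesenchyme were narrower in THC over the list alone, but no list as a whole was by camera. After quantile normalization camera called 4 lists narrower in THC than in Ctrl, namely luminal progenitor and alveolar (adjusted p 0.00693), epithelial mesenchymal transition (0.00485), Wnt and Notch signalling (0.00485) and adipocyte markers (0.0103). None of the 4 passed by camera with median centring at the same preset correlation (adjusted p 0.461, 0.0958, 0.507 and 0.0958). With median centring and an estimated correlation camera gave adjusted p = 0.830, 0.830, 0.857 and 0.607. None passed without centring either. Lpl, which encodes lipoprotein lipase, had 1132 ± 49.5 bp of H3K4me3 in Ctrl and 0 bp in both THC libraries, a log2 change of −2.36 (SE 0.32, adjusted p 0.00249 over the list alone). For genes with 0 bp in THC the size of the log2 change likewise follows from the pseudocount. Over the other settings measured it ran from −4.13 to −0.86 at Lpl. Sqle fell to 1036 ± 133 bp (−0.80, SE 0.07, adjusted p 0.00116 over the list alone), and the Notch ligand gene Dll4 from 999 ± 356 to 0 bp (−2.17, SE 0.32, adjusted p 0.0160 over the list alone). Mgll, whose product breaks down an endocannabinoid, fell from 721.5 ± 27.6 to 0 bp (−1.83, SE 0.37, adjusted p 0.0452 over the list alone). Without Ctrl replicate 1 the adjusted p was 0.162 for Dll4 and 0.306 for Mgll, and Mgll also missed 0.05 without Ctrl replicate 2 (0.226), SR2 replicate 1 (0.0560) or SR2 replicate 2 (0.0510).

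Of the adipocyte markers, 3 of 7 tested genes passed over the list alone, namely Lpl, Thrsp (−1.79, SE 0.39) and Pparg (−1.70, SE 0.41), and Cidea (728.5 ± 216 bp in Ctrl) was also control-only. Of the sterol and lipid metabolism genes, 4 of 25 passed, among them Sqle, the sterol exporter gene Abcg1 (−1.95, SE 0.36) and Elovl6 (−0.49, SE 0.11), while Fasn did not, at 2459 ± 119 bp in Ctrl and 1839 ± 137 bp in THC (adjusted p 0.974 over all regions). In Wnt and Notch signalling 3 of 26 passed, namely Dll4, Heyl (−1.61, SE 0.33) and Wnt5a (−0.47, SE 0.09). The epithelial mesenchymal transition list gave 2 of 17, Twist2 (−2.21, SE 0.39) and Tgfbr2 (−0.63, SE 0.11). Fibroblast markers gave 3 of 4, Col1a1 (−0.86, SE 0.16), Col5a1 (−1.69, SE 0.56) and Cxcl12 (−1.77, SE 0.46). Sox10 (−1.73, SE 0.34), Mgll and the endothelial gene Ramp2 (−1.61, SE 0.36) were also among the 18 of 347 tests that passed adjusted over the list alone. All 18 were narrower, as were 2903 of all regions, against 695 wider, at an unadjusted p under 0.05 by limma. When single libraries were left out in turn, Lpl, Sqle and Cxcl12 passed every time. Without Ctrl replicate 1 the adjusted p missed 0.05 for 12 of the 18 genes (0.0747 to 0.306), without Ctrl replicate 2 for 11 (0.0516 to 0.226) and without THC replicate 1 for 5 (0.0803 to 0.126). Without THC replicate 2 Heyl missed it (0.0695), and without SR2 replicate 1 or 2 Elovl6 did (0.0589 and 0.0506), as did Mgll. Quantile normalization ended 10 of the 18 calls, with smaller changes at Ramp2 (−0.40, adjusted p 0.507), Heyl (−0.41, 0.512), Sox10 (−0.72, 0.295), Mgll (−0.82, 0.291), Thrsp (−0.82, 0.223), Cxcl12 (−0.84, 0.198) and Abcg1 (−1.07, 0.132). Twist2 (0.0658), Col1a1 (0.0538) and Col5a1 (0.0538) ended nearer the threshold. Of the 18 calls, 16 held with a pseudocount of 50 bp and 16 with 1000 bp. Without centring 17 held, and 17 held over regions marked in at least 1 library. All 18 held with only the 4 libraries compared.

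Further list genes were control-only for THC. From the luminal and stem cell lists these were Ly6a (1138 ± 136 bp in Ctrl), Nes (999.5 ± 89.8 bp) and Aldh1a3 (967 ± 127 bp), and from the other lists Nlrc5 (771.5 ± 31.8 bp), an activator gene of MHC class I, Kdr (728 ± 239 bp), a receptor gene of endothelial cells, and Sparc (663 ± 236 bp). Outside the lists the broadest were Wnt3a (1576.5 ± 58.7 bp), Ssbp4 (1552.5 ± 26.2 bp), Mgst1 (1484 ± 697 bp), Foxn1 (1448 ± 672 bp), Galnt6, Tox2 (1384.5 ± 315 bp), Ccrl2 (1366.5 ± 257 bp) and Grin1 (1360 ± 376 bp, shared with Lrrc26). No gene was named as THC-only.

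The THC comparison held 2555 control-only regions (17.5% of the 14612) and 11 THC-only regions, a total of 2566 beside 85 for the split by batch and 148 for the crossed split. Of the control-only regions 27.2% (694) lay at gene ends, against 84.4% of the regions marked in all 4 libraries (odds ratio 0.0692), and 640 protein-coding genes were affected. With 11924 peaks from each library 345 regions were control-only and 46 THC-only, a total of 391 beside 169 and 149, and 4 of the 23 genes named for THC remained control-only (Aldh1a3, Abcg1, Thrsp and Foxn1), against 18 with peaks of −log10 q of at least 5 and 21 with at least 500 bp covered. At that number the log2 change of breadth turned positive for Sox10 (0.37), Wnt5a (1.35), Dll4 (0.37) and Pparg (1.00). The values of Sox10 and Dll4 were identical, as centring alone gives where no Ctrl or THC library has a peak. They therefore do not show wider H3K4me3 in THC.

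Over all regions limma called 0 of 15772 for THC against Ctrl, with 695 wider and 2903 narrower at an unadjusted p under 0.05 (smallest adjusted p 0.128). With a pseudocount of 50 bp it called 1417, without centring 1914 and with only the 4 libraries compared 1929, nearly all narrower. Without THC replicate 2 it called 489 wider and 1694 narrower, and 96 over the list alone, which fell to 4 without Ctrl replicate 1 and to 6 without Ctrl replicate 2. The Lpl and Sqle calls held in all 14 and all 16 other settings measured. With the replicate block the adjusted p over the list alone was 0.0647 for Heyl, 0.0647 for Wnt5a, 0.0608 for Mgll and 0.0542 for Sox10.

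**Figure D2:**
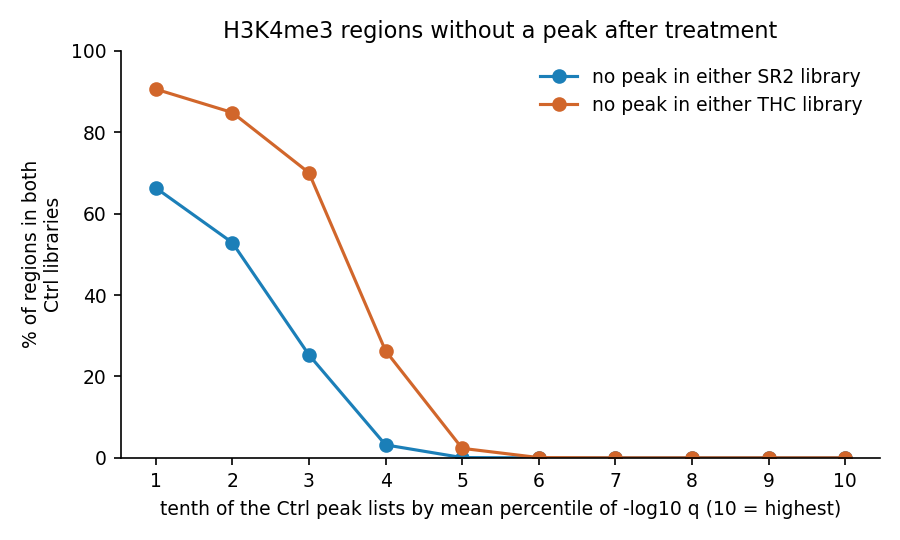
Percent of the H3K4me3 regions marked in both Ctrl libraries that had no peak in either library of a treatment (y axis), by the mean percentile of the authors' −log10 q in the 2 Ctrl lists (x axis, 10 bins, 1 lowest to 10 highest). The share is 66.3% for SR2 and 90.6% for THC in bin 1, and 0 from bin 6 for SR2 and from bin 7 for THC.

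The control-only regions were among the weakest Ctrl peaks. Ranked by the authors' −log10 q within each Ctrl list, their median percentile was 20.1 and 14.1 for SR2 and 25.5 and 18.1 for THC (Ctrl replicates 1 and 2), and 0 and 0 of the SR2 regions and 5 and 1 of the THC regions reached the upper part of the list above the median. They were also short, with a median of 452 bp for SR2 and 508 bp for THC against 1178 and 1240 bp in regions marked in all 4 libraries.

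Peak numbers were lower in treated libraries than in Ctrl in both batches, a difference whose exact permutation test cannot reach 0.05 with 2 libraries per group. The SR2 to Ctrl ratio of mean peak numbers was 0.862 (0.806 in batch 1 and 0.924 in batch 2), that of THC to Ctrl 0.722 (0.649 and 0.805), and that of THC to SR2 0.838 (0.805 and 0.871). Each exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow, and both treatments together against Ctrl gave 0.133, the smallest that 2 against 4 allow. The covered length was 17.4 ± 1.72 Mb in Ctrl, 14.1 ± 1.14 Mb in SR2 and 10.7 ± 2.35 Mb in THC, and the mean peak was 998 ± 20.2, 943 ± 59.3 and 845 ± 125 bp.

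THC and SR2 were then compared with each other, and their control-only regions with one another. Dll4, with 1294 ± 215 bp in SR2 and 0 bp in THC, was narrower in THC (−2.65, SE 0.32, adjusted p 0.00551 over the list alone), as were Sox10 (−2.17, SE 0.34, adjusted p 0.0121) and Col1a1, a collagen gene (−0.97, SE 0.16, adjusted p 0.00372). All 3 adipocyte genes named above were narrower too, Lpl by −1.74 (SE 0.32), Thrsp by −1.60 (SE 0.39) and Pparg by −1.34 (SE 0.41). Tgfbr2, Cldn4, Wnt5a, Col5a1, Lcp1 and Ramp2 were the other narrower genes, and Pkp3 was wider (0.38, SE 0.08), which made 13 of 347 adjusted over the list alone. Each of the 13 calls ended without some single library. Those of Cldn4 and Pkp3 ended whichever of the 6 was left out (adjusted p 0.0573 to 0.328), that of Dll4 without SR2 replicate 1 (0.0740), and those of Sox10 and Col1a1 without SR2 replicate 2 (0.0787 and 0.0627). Col5a1 missed 0.05 without SR2 replicate 1 or 2 (0.0721 and 0.183), Lpl without Ctrl replicate 1 or 2 (0.0608 and 0.0659), Thrsp and Ramp2 without Ctrl replicate 1 or 2 or SR2 replicate 1 (0.0659 to 0.135). Tgfbr2 missed it without SR2 replicate 1 or 2 or THC replicate 1 (0.0663 to 0.140), Lcp1 when any Ctrl or SR2 library was left out, and Wnt5a and Pparg when any library but THC replicate 2 was (together 0.0659 to 0.217). With the replicate block 7 tests passed, and the adjusted p over the list alone rose to 0.0536 for Pparg, 0.0537 for Ramp2, 0.0588 for Pkp3, 0.0702 for Wnt5a, 0.0723 for Tgfbr2 and 0.0949 for Lcp1. Quantile normalization ended the calls of Lpl (−0.93, adjusted p 0.106), Pparg (−1.03, 0.106), Thrsp (−0.79, 0.327), Ramp2 (−0.57, 0.320), Lcp1 (−0.52, 0.218) and Sox10 (−1.58, 0.0510). The sign for Lpl turned (0.23) with only peaks of −log10 q of at least 5. Lpl had no peak in either THC library, so that value may come from the centring and does not show wider H3K4me3. Without centring 10 of the 13 calls held and 0 genes were called wider, so the Pkp3 call ended. The lowest log2 change of Pkp3 over the settings measured was 0.14. Leaving out Ctrl replicate 1 or 2 gave 6 and 6 calls, SR2 replicate 1 or 2 gave 4 and 6, and THC replicate 2 gave 77. Over all regions limma called 0 (1189 without THC replicate 2), with 290 wider and 1079 narrower at an unadjusted p under 0.05.

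Between the treatments, 616 regions were SR2-only and 13 THC-only, a total of 629 beside 443 for the split by batch and 150 for the crossed split. With equal numbers of peaks the total was 246 beside 278 for the split by batch. Of the 1146 control-only regions of SR2, 1022 (89.2%) were also control-only for THC, Galnt6, Cxcl12, Heyl, Ptgs2, Sox2, Lgr5 and Lhx2 among the genes. Independent lists of these lengths drawn from all 24596 regions would share 119. That reference is too low, since control-only regions can come only from the 14612 regions marked in both Ctrl libraries. Simulated treatments with no effect against the same controls shared 123 (99 to 157). The simulated lists held 489 regions each on average and not the real numbers. Neither reference was matched on peak strength, and the control-only regions of both treatments were among the weakest Ctrl peaks. In strength bin 1, 66.3% of regions were control-only for SR2 and 90.6% for THC, and in bin 2, 52.9% and 84.8%. The excess is therefore no measure of a shared response. The 2 Ctrl libraries were not split between the treatments, which would leave 1 in each part. Part of the excess may come from the shared controls and part from shared peak strength.

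**Figure D3:**
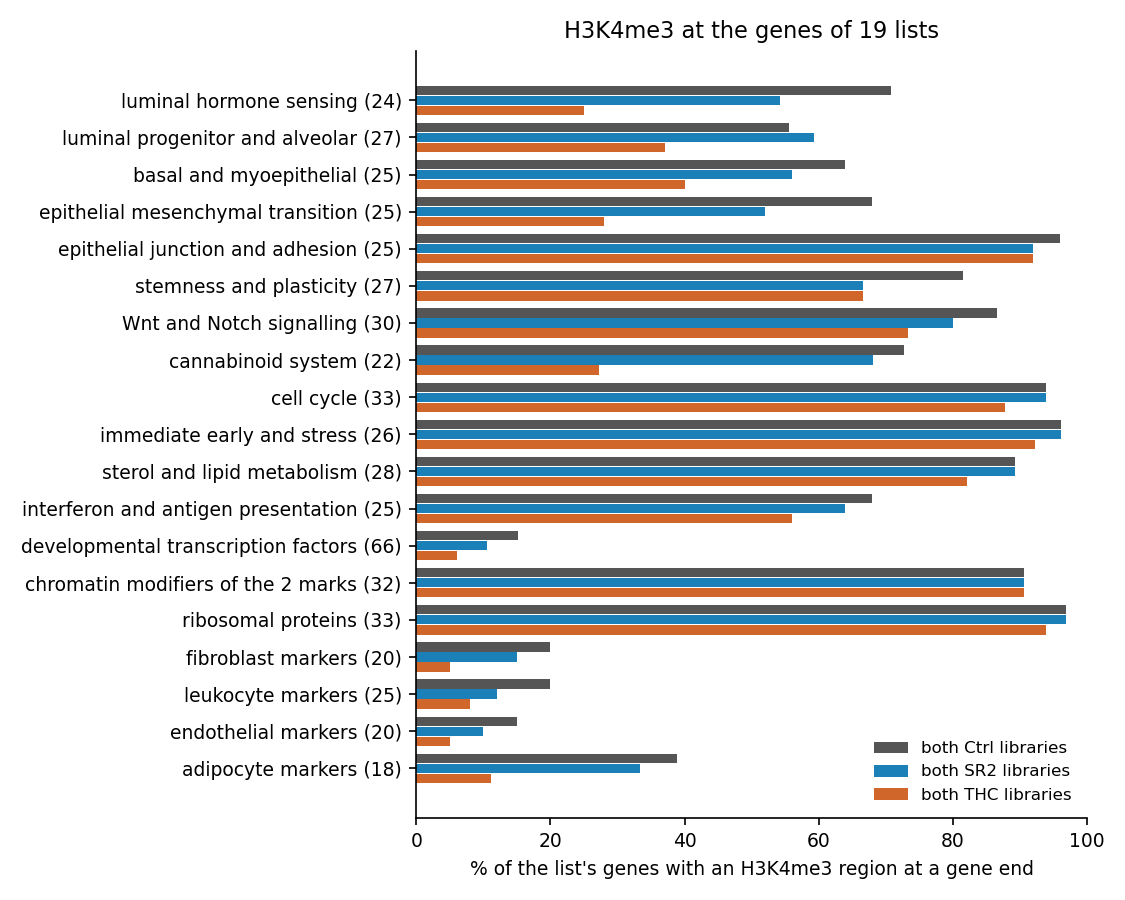
Percent of the genes of each list (x axis) that had an H3K4me3 region at a gene end in both libraries of Ctrl, SR2 or THC (bars), with the number of list genes in brackets (y axis). Both Ctrl and both THC libraries marked 17 and 6 of 24 luminal hormone sensing genes, and 29 and 29 of 32 chromatin modifier genes.

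The number of members marked in all 6 libraries was counted for each list, without a test between lists. Among 29 marked chromatin modifier genes all 29 had a peak in all 6 libraries, as had 31 of 32 ribosomal protein genes, 29 of 31 cell cycle genes, 24 of 25 immediate early and stress genes, 23 of 25 junction and adhesion genes and 23 of 26 sterol and lipid genes. Broad examples were Cdk6 (3566.5 ± 3.54 bp in Ctrl), Fosb (2890.5 ± 117 bp), Rpl7 (2440.5 ± 274 bp, shared with Rdh10), Esrp2 (3419.5 ± 79.9 bp) and Jup (2875.5 ± 53.0 bp). Stemness and plasticity genes (18 of 22), Wnt and Notch genes (22 of 26) and interferon and antigen presentation genes (14 of 21) followed, with Myc at 3355.5 ± 153 bp in Ctrl, Sox4 at 3122 ± 311 bp, Jag1 at 3457.5 ± 189 bp and the region shared by Psmb9 and Tap1 at 1738 ± 24.04 bp. Fewer members were marked throughout in the luminal hormone sensing list (6 of 17, including Cd24a and Xbp1), the luminal progenitor and alveolar list (10 of 16, including Btn1a1 and Rel), the basal and myoepithelial list (10 of 18, including Jag2 and Tcf7l2), the epithelial mesenchymal transition list (7 of 17, including Mmp14 and Tgfb1) and the cannabinoid system list (6 of 16, Cnr2 and Ppard among them). The region counted for Cnr2 is the one shared with Fuca1.

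Among markers of other cell types, fibroblast markers had a region at 4 of 20 genes, leukocyte markers at 6 of 25, endothelial markers at 4 of 20 and adipocyte markers at 8 of 18, and developmental transcription factors at 21 of 66. In both Ctrl libraries these lists held 4, 5, 3, 7 and 10 marked genes, in both SR2 libraries 3, 3, 2, 6 and 7, and in both THC libraries 1, 2, 1, 2 and 4. Col1a1, Lcp1, Ikzf1, Flt1, Cebpa, Pnpla2, Irx3 and Irx5 were marked in all 6 libraries.

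No list passed Fisher's exact test among control-only or treated-only regions in 76 tests, 5 of which had an unadjusted p under 0.05. The smallest adjusted p, 0.137, belonged to luminal hormone sensing in THC (5 of 17, 29.4% against 6.14% of other gene-end regions, odds ratio 6.37) and epithelial mesenchymal transition in SR2 (3 of 17, 17.6% against 1.84%, odds ratio 11.4). The others were adipocyte markers in THC (3 of 7, adjusted p 0.173), endothelial markers in THC (2 of 3, adjusted p 0.209) and developmental transcription factors in SR2 (2 of 10, adjusted p 0.215). Random lists of the same peak strength in Ctrl held 4.39 luminal hormone sensing and 2.05 epithelial mesenchymal transition hits on average, and 0 of 38 tests against them passed, with a smallest adjusted p of 0.418. Such random lists were not drawn for the runs that leave out a library, where 1 library stands for its group. Without THC replicate 2 that library is THC replicate 1, which had the fewest H3K4me3 peaks (11924). Without THC replicate 2, 4 lists passed for THC, namely luminal hormone sensing (11 of 17, adjusted p 0.000160), cannabinoid system (10 of 16, 0.000374), epithelial mesenchymal transition (9 of 17, 0.00422) and adipocyte markers (5 of 7, 0.0165). Without Ctrl replicate 1 developmental transcription factors passed for SR2 (4 of 13, 0.0213), and without Ctrl replicate 2 for SR2 (8 of 16, 2.53e-05) and THC (8 of 16, 0.00249).

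By camera, 3 of 57 tests of breadth passed. Adipocyte markers were narrower in THC than in SR2 (7 of 7 genes, median −0.70, adjusted p 0.00849). Chromatin modifier genes were wider relative to the other regions in THC (20 of 29 genes, median 0.12, adjusted p 0.00849) and in SR2 (23 of 29, median 0.09, adjusted p 0.0231) against Ctrl, but without centring their medians turned to −0.26 and −0.05. None of the 3 held with an estimated correlation, where adjusted p = 0.607 for each. The chromatin modifier list includes Kdm6b, which encodes an H3K27 demethylase and went the other way, from 2783 ± 157 bp in Ctrl to 1494.5 ± 472 bp in SR2 and 988 ± 437 bp in THC (adjusted p 0.235 and 0.128 over all regions). With the replicate block the luminal progenitor and alveolar list also passed as narrower in THC than in SR2 (adjusted p 0.0415, against 0.0569 without it; 13 of 15 regions narrower), but not with an estimated correlation (adjusted p 0.607, without the block). Quantile normalization also gave that call (adjusted p 0.00485) and kept that of adipocyte markers in THC against SR2 (0.00592), but ended both chromatin modifier calls (0.757 for THC and 0.386 for SR2). Without Ctrl replicate 1, Ctrl replicate 2, SR2 replicate 1 and THC replicate 2 in turn, camera called 6, 8, 1 and 5 lists.

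H3K27me3 was compared to ask whether the repressive mark differs after treatment. It lay over genes of developmental transcription factors, 57 of 66 of which had a peak in at least 1 library (86.4% against 11.7% of all protein-coding genes, Fisher's exact test, odds ratio 49.0, adjusted p 9.22e-43 over 19 lists). Regions marked in both Ctrl libraries and in neither SR2 library lay at Sp8 (2002.5 ± 92.6 bp in Ctrl), Hoxb13 (1647 ± 48.1 bp), Uncx (1650.5 ± 436 bp), Cdh2 (1273 ± 349 bp), Tbx2 (1241.5 ± 374 bp, shared with Bcas3), Gata6 (1073 ± 74.95 bp) and Pparg (917.5 ± 142 bp). For THC such regions lay at Uncx, Cdh2, Tbx2, Pparg, Neurod2 (1408.5 ± 428 bp), Nkx6-1 (1323.5 ± 146 bp) and the pioneer factor gene Foxa1 (584.5 ± 243 bp). Tbx2 had another H3K27me3 peak, outside its control-only region, in THC replicate 1. These are descriptions of the lists and not called changes, because the batches differed more than the treatments.

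For SR2, 76 of the 187 H3K27me3 regions marked in both Ctrl libraries (40.6%) were control-only and 7 were SR2-only, a total of 83, whereas the split by batch gave 133. Besides those above, further control-only regions lay at Zic5, Pou3f2, Prdm12, Otp, Neurog2, Hoxa9 and Hoxa10, Lin28b and Foxd3. The SR2-only regions were near Sfi1, Ist1 and Zfp821, Sertad2 and Cobl, and 3 had no protein-coding gene within 5 kb, the longest at chromosome 1 from 31791872 to 31794464. For THC, 73 regions (39.0%) were control-only and 4 THC-only, a total of 77 beside 148 for the split by batch, with Gata2, Otp, Cacna2d1, Nkx2-9, Neurog2, Barx1, Barhl2, Dlx5, Hoxc8, Hoxd9 and Hoxd10, Neurog1, Foxd3 and Hoxd3 among the genes. Of these, Neurog2, Hoxd9 and Hoxd10 had another H3K27me3 peak in THC replicate 1. The THC-only regions were near Adk and Ceacam15 and at 2 places without a protein-coding gene within 5 kb. The treatments shared 45 control-only regions, and 10 regions were SR2-only and 3 THC-only between them. With equal numbers of peaks within each batch, 7 regions were control-only and 8 SR2-only, and 8 control-only and 6 THC-only.

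**Figure D4:**
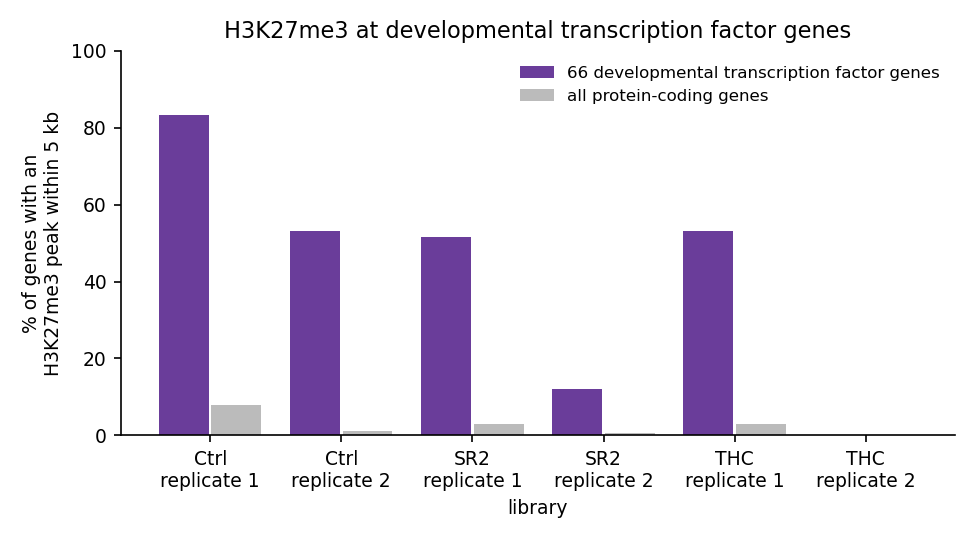
Percent of genes with an H3K27me3 peak over the gene or its 5 kb of flank (y axis) in each of the 6 libraries (x axis), for 66 developmental transcription factor genes and for all 21883 protein-coding genes. The list stands above all genes in 5 libraries, from 12.1% against 0.516% to 83.3% against 7.93%, and has 0 genes in THC replicate 2.

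By library, 55 and 35 of the 66 developmental transcription factor genes had H3K27me3 in Ctrl, 34 and 8 in SR2, and 35 and 0 in THC. Fisher's exact tests of the list in each library, chosen after the data had been examined, gave odds ratios of 59.9 and 117 in Ctrl, 36.6 and 28.5 in SR2, and 37.5 and 0 in THC, with adjusted p-values of 1.75e-49, 8.83e-51, 2.19e-34, 2.11e-09, 2.62e-35 and 1. No other list passed, the nearest being stemness and plasticity (8 of 27, adjusted p 0.0931) and luminal hormone sensing (7 of 24, adjusted p 0.106). Of the remaining lists, chromatin modifiers had 7 genes with a peak in any library, Wnt and Notch signalling and sterol and lipid metabolism 6 each, cell cycle and fibroblast markers 5 each, and epithelial mesenchymal transition and the cannabinoid system 4 each. The luminal progenitor, basal, immediate early, ribosomal, leukocyte and endothelial lists had 2 each, and junction, interferon and adipocyte genes 1 each.

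The number of H3K27me3 peaks was 1549.5 ± 1644 in Ctrl, 498.5 ± 483 in SR2 and 527 ± 646 in THC, with SDs close to or above the means. The ratio to Ctrl was 0.322 for SR2 (0.310 and 0.406 in batches 1 and 2) and 0.340 for THC (0.363 and 0.181), each with an exact two-sided permutation p of 0.667. Covered length gave 0.308 for SR2 (0.308 and 0.312) and 0.347 for THC (0.374 and 0.182), also with an exact p of 0.667. Within each batch both treatments had fewer peaks than Ctrl. Without Ctrl replicate 1 the ratios of peak numbers turned to 1.29 and 1.36, because a Ctrl library of batch 2 then stood against treated means that included batch 1.

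Genes marked by both H3K4me3 and H3K27me3 at their ends numbered 722 and 47 in the Ctrl replicates, 321 and 27 in SR2, and 273 and 5 in THC. The numbers for independent lists were 495 and 49.9, 187 and 20.2, and 174 and 2.93, and Fisher's exact test gave odds ratios of 3.36 (p = 1.43e-57) and 0.883 (p = 0.607) in Ctrl, 6.13 (p = 1.92e-48) and 2.10 (p = 0.0361) in SR2, and 2.99 (p = 2.32e-24) and 5.25 (p = 0.116) in THC. Both Ctrl libraries shared 32 such genes, including the list genes Pparg, Lin28b, Tbx2, Cbx8 and Cdh2, and both SR2 and both THC libraries shared 14 and 4. The 4 genes shared in THC, 4931408C20Rik, Slc30a4, Lars2 and Tmem267, had both marks in all 6 libraries. Each lies at an H3K27me3 region found in all 6 libraries. As described below, such regions may be signal that does not depend on the antibody. In the SR2 lists Cdh2 had a peak of neither mark and Pparg an H3K4me3 peak in both libraries and no H3K27me3 peak. These absences come from no test. The SR2 lists for H3K27me3 held 840 and 157 peaks, and the H3K4me3 difference at Cdh2 did not remain with equal numbers of peaks.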

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

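The tests of sequencing depth and of the developmental promoters below were chosen only after the result had been seen.

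On sequences outside the comparisons, H3K4me3 peaks covered more bp in some treated groups than in Ctrl. On the mitochondrial sequence, peaks covered 11455.5 bp on average in SR2 and 11462 bp in THC against 10423 bp in Ctrl, a ratio of 1.10 for each. On unplaced or random sequences they covered 12823 bp in SR2 against 10768 bp in Ctrl, a ratio of 1.19, with 13157 and 12489 bp in the SR2 libraries and 9495 and 12041 bp in the Ctrl libraries. The THC libraries, with 9850 and 17788 bp there, lay on both sides of Ctrl replicate 2.

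Far more H3K4me3 regions were found in Ctrl alone than in either treatment alone (1146 against 31 for SR2, 2555 against 11 for THC). A control-only region has no peak in either library of a treatment, so lower depth as the whole cause needs both libraries below Ctrl in background pileup. Of the 2 SR2 libraries 0 lay below both Ctrl libraries, and of the THC libraries 1 did (0.726 of the Ctrl mean) while replicate 2 was at 1.47, which argues against it for both treatments, though depth may add to the pattern in THC replicate 1. A common factor of weaker enrichment per library predicted 0.307 of the control-only regions for SR2 and 0.532 for THC. The SR2 value lay below the bound set beforehand for rejecting such a factor, and the THC value above it. Between replicates of 1 group, with no difference of treatment, the same model predicted 0.0526 to 0.694 of the absent regions in 6 directions. That check counts regions absent from 1 library and not from both of a group, so it cannot tell whether the bound was too high. In the stronger regions marked in all 6 libraries, at gene ends, the median summit pileup relative to background was 0.383 and 0.634 of Ctrl in SR2. In THC it was 0.272 and 0.320 (replicates 1 and 2). Away from gene ends it was 0.386 and 0.629 in SR2, and 0.271 and 0.319 in THC. Enrichment at strong regions was thus weaker in every treated library, to much the same degree in both places. Whether a common factor of weaker enrichment accounts for much of the excess stays open for both treatments. A change that spares gene ends beyond that factor predicted a ratio well above 1. It was 0.933 for THC (0.878 to 0.997 over resampled regions) and 1.21 for SR2 (1.06 to 1.38). These intervals leave out the spread between libraries, and the ratios between replicates ranged from 0.957 to 1.57. The SR2 value lies inside that range, which leaves such a change open. The THC value lies just under the range, which gives no sign of such a change but does not exclude it. An effect of either treatment on H3K4me3 stays open as the biological explanation, and was not separated from the efficiency of each reaction.

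The 26 H3K27me3 regions found in all 6 libraries may be signal that does not depend on the antibody, as from repeats or extra copies of a sequence. Of these, 53.8% (14) overlapped an H3K4me3 region of all 6 libraries away from gene ends, against 2.31% of the H3K27me3 regions found in 1 library. No biological explanation was tested.

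H3K27me3 regions overlapped H3K4me3 regions more often than by chance. Those found in 1 library did so in 1011 of 3635 cases, 22.99 times the mean of 44.0 after shifting them along their chromosomes, which is consistent with cutting of open chromatin in the H3K27me3 reactions. Both marks on promoters of silent developmental genes predicted a share of overlap at the developmental transcription factor list at least that of other regions. Regions at that list overlapped in 17.7% of cases (20 of 113) against 32.8% of the other regions, a ratio of 0.539. The other regions held 1337 overlaps, so most of the overlap could not lie at this list. The test does not cover developmental genes outside it. That ratio lies between the bounds set for it, so these genes could still contribute, and the explanations are not exclusive.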

How the results depend on the processing

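Of the alternatives below, those for peak numbers, for gene lists among control-only regions, for the overlap of the treatments, for the breadth of gene lists without centring or after quantile normalization, and for calls over the list alone were chosen after seeing the data, as were the runs that leave out a library for these results. The windows planned around transcription starts were not run as written, since no starts were used, and windows of 250 bp and 2.5 kb around gene ends took their place. Where no cause is named, the cause was not tested.

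The H3K4me3 peak number stayed lower in both treatments than in Ctrl when any single library was left out, with ratios of 0.816 to 0.912 for SR2 and 0.684 to 0.765 for THC. The direction of the H3K27me3 totals turned in 1 run. Without Ctrl replicate 1 the ratio of peak numbers turned to 1.29 for SR2 and 1.36 for THC and that of covered length to 1.10 and 1.24, because a Ctrl library of batch 2 then stood against treated means that included batch 1, whereas within each batch all 4 ratios of peak numbers were below 1 (0.310 and 0.406 for SR2, 0.363 and 0.181 for THC). Over all such runs the ratios of peak numbers spanned 0.101 to 1.29 for SR2 and 0.0452 to 1.36 for THC, and those of covered length 0.0870 to 1.10 and 0.0507 to 1.24.

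With only H3K4me3 peaks of −log10 q of at least 5, 7 regions were SR2-only and 2 THC-only, and 1 gene list passed (fibroblast markers in THC, 4 of 4, adjusted p 0.00209). With the same number of peaks from each library there were 139 control-only and 68 SR2-only regions, 345 control-only and 46 THC-only regions, 246 regions that differed between THC and SR2, and 81 shared control-only regions. Equal lists take out the weakest Ctrl peaks and push the counts of both directions together by construction, so these counts do not show why Ctrl had more. With at least 500 bp covered, 679 regions were control-only and 6 SR2-only for SR2, and 1 was THC-only. Leaving out a library raises these counts by construction, since 1 library then stands for its group. The ranges were 1380 to 4133 control-only and 60 to 1985 SR2-only regions for SR2, 2744 to 6063 and 19 to 1001 for THC, 1722 to 2935 regions that differed between THC and SR2, 1046 to 3936 shared control-only regions, and 0 to 4 gene lists.

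Breadth calls over all regions by limma, 0 in each comparison, depended on the scale. With a pseudocount of 50 bp there were 1059 for SR2 and 1417 for THC against Ctrl, of which 27 and 20 were wider. No centring gave 994 and 1914, since the lower breadth of the treated libraries then counts as change. For THC against Ctrl, regions marked in at least 1 library gave 39, only the 4 libraries compared gave 1929, and equal numbers of peaks gave 4. Leaving out a library gave 0 to 2183 for THC against Ctrl and 0 to 1189 for THC against SR2, the highest without THC replicate 2 in both, where THC replicate 1 was assumed to vary like the libraries of the other groups.

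The camera calls, 3 as reported, came to 0 with an estimated correlation, 1 with no centring, 6 after quantile normalization and 1 to 8 when a library was left out. Over the list alone, the 4 calls for SR2 against Ctrl came to 9 with a pseudocount of 50 bp, 2 in regions marked in all 6 libraries, 8 with only the 4 libraries compared, 8 with −log10 q of at least 5, 7 with equal numbers of peaks and 1 to 7 when a library was left out. The 18 calls for THC against Ctrl came to 9 in regions marked in all 6 libraries, 33 with no centring, 10 after quantile normalization, 33 with only the 4 libraries compared, 7 with equal numbers of peaks and 4 to 96 when a library was left out. The 13 calls for THC against SR2 came to 21 in regions marked in at least 1 library, 8 in regions marked in all 6, 20 with no centring, 7 after quantile normalization, 6 with only the 4 libraries compared and 4 to 77 when a library was left out. The sign turned at Lpl for THC against SR2 with −log10 q of at least 5 (0.23). With equal numbers of peaks it turned for THC against Ctrl at Sox10 (0.37), Wnt5a (1.35), Dll4 (0.37) and Pparg (1.00). The identical values of Sox10 and Dll4 are what centring alone gives where no library compared has a peak. The value of Lpl, without a peak in either THC library, may have the same origin. These 3 values do not show wider H3K4me3 in THC.

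The replicate block left 7 calls over the list alone for THC against SR2. It ended the calls of Heyl for SR2, of Heyl, Wnt5a, Mgll and Sox10 for THC against Ctrl, and of Pparg, Ramp2, Pkp3, Wnt5a, Tgfbr2 and Lcp1 for THC against SR2, and it added the luminal progenitor and alveolar list for THC against SR2 by camera. The block ended no other call, 30 of 42 results with a block being the same. It also added calls over the list alone, which are not named here. THC against Ctrl had 19 calls with the block, with 14 of the 18 kept. SR2 against Ctrl had 4, with 3 of the 4 kept. Counts of control-only and treated-only regions come from no test, so no block could be fitted to them.

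For H3K27me3, −log10 q of at least 3 left 8 control-only and 3 SR2-only regions for SR2, 8 control-only and 1 THC-only region for THC, and 1 that differed between THC and SR2. Equal numbers of peaks within each batch left 7 control-only regions for SR2, 8 for THC, and 6 that differed between the treatments, and coverage of at least 50% of the region left 4 SR2-only. Batch 1 alone gave 2468 control-only and 593 SR2-only regions, 2458 control-only and 728 THC-only regions, and 1433 that differed, and batch 2 alone gave 325, 96, 339, 24 and 166. With a library left out these counts ran from 84 to 2447, 12 to 571, 81 to 2437, 5 to 703 and 57 to 782, again because 1 library stands for a group. The 57 developmental transcription factor genes with a peak came to 14 with −log10 q of at least 3 and to 49 without flank. By Fisher's exact test, genes with both marks within 2.5 kb of a gene end numbered 60 in Ctrl replicate 2 (p = 0.0174, fewer than the 73.8 of independent lists) and 10 in THC replicate 2 (p = 0.0123). With H3K4me3 peaks of −log10 q of at least 5 they numbered, by the same exact test, 34 in Ctrl replicate 2 (p = 0.00383, fewer than 48.2) and 26 in SR2 replicate 2 (p = 0.0374). Sequencing depth, unknown for H3K27me3, limits the number of its peaks and every count made from them.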

Other observations

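None of the values in this part answers a comparison between groups, and the genes were chosen after their values had been seen, by the width of their regions in Ctrl.

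The widest H3K4me3 regions of the Ctrl libraries are given by rank, and no test of their genes as a group was run. The region at Brd2 and H2-DMa (mm10 chromosome 17, 34117553 to 34122994) was covered over 4792 ± 320 bp in Ctrl, 3908 ± 181 bp in SR2 and 2583 ± 1621 bp in THC (mean ± SD, n = 2). Tob2 followed with 4152 ± 50.9 bp in Ctrl, the phosphatase gene Dusp7 with 4108 ± 87.7 bp, and Mxi1, which encodes a partner of MAX, with 3930 ± 97.6 bp. At Vegfa (chromosome 17, 46028714 to 46032831), the gene of an angiogenic growth factor, the values were 3886 ± 328 bp in Ctrl, 2591 ± 139 bp in SR2 and 2431.5 ± 593 bp in THC. Efna5, Dusp4, Midn, Cdk6 and Anp32a completed the 10 widest, each marked in all 6 libraries.

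The longest H3K27me3 region of all 6 libraries lay on chromosome 17 from 39843150 to 39848748. It was covered over 5576 ± 32.5 bp in Ctrl, 5119.5 ± 646 bp in SR2 and 5566 ± 38.2 bp in THC. No protein-coding gene lay within 5 kb, and other kinds of gene were not searched. A region on chromosome 15 from 75085504 to 75087038 was covered over 1535 bp in each of the 6 libraries. Both regions also overlapped an H3K4me3 region found in all 6 H3K4me3 libraries. Among the 26 H3K27me3 regions found in all 6 libraries, 3 had the gene Sfi1 within 5 kb. As said above, these 26 regions may be signal that does not depend on the antibody.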
